A study of Mus musculus with 2 samples.

How the data were processed

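RNA from 2 cultures of mouse mammary carcinoma cells was measured on Affymetrix expression arrays, with 1 array for the 4T1 parental line and 1 array for the 4T1-3R liver metastatic cells, called 4T1-3R_L here. Per the labels' protocols, total RNA was purified on columns and converted to biotin-labelled cRNA by the array maker's standard procedure. The series' value table holds 45101 probe sets on each array, of which 64 are control probe sets.

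The deposited values are probe set intensities on a linear scale, computed with MAS5, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and then scales each array as a whole. The MAS5 version, its scaling target and the detection calls are not given in the sources used here. The mean signal after trimming 2% of probe sets at each end was 500.003 on both arrays, so the values had already been brought to a common trimmed mean and the scaling step applied here left them as they were. The median signal was 87.4 on the parental array and 93.3 on the 4T1-3R_L array.

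Probe sets were named from the platform annotation given with the value table. A single gene symbol was given for 34958 probe sets, several symbols for 932, and 9160 probe sets other than controls were not listed there and stay unnamed here. Of the single-gene probe sets, 34754 had an Entrez identifier in the RefSeq gene table of the GRCm38.p6 assembly, and 0 of these needed a new symbol. The build behind the array annotation is not given in the sources used here. That table therefore served only for gene names, chromosomes, the order of neighbouring genes and local gene density, counted within 1 Mb on each side.

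Signals under a floor of 90.6, the median of all scaled signals of both arrays, were set to the floor before taking log2. With no detection calls to use, the floor stood in for the background, and 22299 parental and 22805 4T1-3R_L probe sets reached it. A gene was represented by its single-gene probe set with the highest mean log2 signal, and counted as measured where that probe set reached the floor on at least 1 array. This gave 11135 measured genes of 18193 with a single-gene probe set, 10070 of them at or above the floor on both arrays. The log2 ratio is the 4T1-3R_L signal over the parental signal. Where 1 array lay under the floor, the fold is a lower bound against the floor and is given as at least that fold.

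With 1 array in each group there is no replicate spread, so no test was run and no p-value is given; all values describe these 2 arrays. Counts were taken of genes at least 2-fold and at least 4-fold apart. For each of 30 gene lists, the median log2 ratio of its measured members was set against the median of all measured genes, and ranked among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. A list median beyond the 2.5 or the 97.5 percentile is called outside the random lists. Lists with fewer than 3 measured members were not ranked.

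The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the highest and the 12 with the lowest log2 ratio among genes above the floor on both arrays, leaving out genes whose second probe set had the opposite sign and predicted or clone symbols. It also named the 6 largest lower bounds in each direction, up to 4 members of each list with the largest log2 ratios in size, and a set of control and marker genes. Members of a list outside this rule are named where a count was 5 or fewer, and those were chosen after their values were seen.

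The alternatives fixed beforehand were median centring, quantile normalization and intensity-dependent loess of the log2 ratios, a floor at the 40th or 60th percentile, a pseudocount of 32 in place of the floor with and without the filter on measured genes, the median over a gene's probe sets, and only probe sets whose names end in plain _at. Scaling of the arrays to the hybridisation control probe sets was added after the data were seen. Hybridisation controls are labelled bacterial and phage cRNAs added to the hybridisation mix, and poly-A controls are bacterial transcripts added to the RNA before labelling.

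The procedure was tested on simulated data made from these arrays, with 200 of 18193 genes changed and a spread of 0.54 on the log2 scale, which is the spread between the real arrays and so includes real differences. The 200 were drawn from genes at or above the floor on both arrays, 40 for each size of change. The rates therefore do not cover genes under the floor on 1 array. A true log2 change of 1 was called at least 2-fold in 35% of genes and of -1 in 52.5%, against 92.5% at 2, 97.5% at -2 and 100% at 3. Of 10802 unchanged genes, 619 (5.73%) came out at least 2-fold apart and 3 at least 4-fold apart. Of 100 unchanged lists of 25 randomly drawn genes, 5 fell outside the random lists, and 98 of 100 lists shifted by 0.5 did. The 5 follow from how the ranking is built, since random lists were ranked among random lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The number of arrays limits the precision of every value.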

Results

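Gene expression was compared between 2 cell populations of mouse mammary carcinoma. The 4T1 line comes from a mammary tumour of a BALB/c mouse and spreads from the mammary fat pad to distant organs, liver included. The 4T1-3R liver metastatic cells, called 4T1-3R_L here, are derived from it and were recovered from liver metastases in mice; both populations were grown in culture and their total RNA was hybridised, 1 array for each. The comparison asks which genes differ between the liver-metastatic cells and the line they came from. There were no replicates, so each value describes these 2 arrays, and a difference cannot be set against a spread between cultures.

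Dmp1, a phosphoprotein of bone and dentin matrix, had a signal of 95.5 in parental cells and 7520 in 4T1-3R_L cells, a 78.7-fold difference or a log2 ratio of 6.30. The parental signal is close to the floor of 90.6, and the log2 ratio was 5.48 with a floor at the 60th percentile, 4.73 on its second probe set and 3.60 with plain _at probe sets. Nptx1, a secreted pentraxin, was 38.0-fold higher (log2 ratio 5.25, and 4.32 on its second probe set), the matrix metalloproteinase Mmp3 was 21.4-fold higher (554 against 11854) and Mgp, matrix Gla protein, was 20.9-fold higher. The parental signal of Mgp, 99.3, was also close to the floor, and its log2 ratio of 4.38 was 3.62 with a floor at the 60th percentile. In the other direction, the tight junction claudin Cldn7 was 36.0-fold lower in 4T1-3R_L cells (5432 against 151) and the basal keratin Krt14 was 31.2-fold lower (5324 against 171).

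Of 11135 measured genes, 693 (6.22%) were at least 2-fold higher in 4T1-3R_L cells and 499 (4.48%) at least 2-fold lower, while 114 and 50 were at least 4-fold higher and lower. Scaling the arrays to the hybridisation controls instead, an alternative added after the data were seen, gave 250 higher and 2288 lower at 2-fold, and 58 higher and 150 lower at 4-fold. That scaling moved the median of all measured genes from -0.01 to -0.54 on the log2 scale, so the balance of higher and lower genes depends on the scaling, and gene groups are described relative to the median measured gene. Under it the medians of the mesenchymal (-0.07), receptor (-0.08), MHC class I (-0.08), glycolysis (-0.09), immediate early (-0.06) and NRF2 (-0.35) lists were themselves negative, though still above the median gene. Together 1192 genes (10.7%) were at least 2-fold apart. In simulated arrays 5.73% of unchanged genes were, but their spread was taken from these same 2 arrays, real differences included. The 2 shares therefore do not measure an excess over noise. The signals of 7036 genes (63.2%) lay within 0.5 of each other on the log2 scale.

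Probe sets of the same gene gave a check of the arrays, not of the cells. Among the 628 genes at least 2-fold apart with another measured probe set, that probe set had the same sign in 591 (94.1%) and was itself at least 2-fold apart the same way in 266 (42.4%). Of the genes named below as at least 2-fold apart, a second probe set was under 2-fold in Wnt7a (log2 ratio -0.02), Vegfa (0.07), Pfkp (0.19), Jag1 (-0.20), Pdia6 (0.26), Psat1 (-0.34), Cmpk2 (-0.34), Scd1 (0.41), Idi1 (-0.43), H2-K1 (0.73), Cd44 (0.91) and Lgr6 (0.91), and in those whose second value is given where they are named. Besides those given where they are named, it was at least 2-fold apart but smaller by over 1.5 times in Mal (-2.73), Hspb1 (-2.001), Bst1 (-1.95), Fbln1 (1.79), Col5a1 (1.73), Fosl1 (1.49) and Pdgfra (1.31). It was larger by over 1.5 times in Egln3 (3.64) and S100a16 (4.46). No second measured probe set existed for Mmp3, Mgp, Cldn7, Ctsw, Esrp1, Slpi, Ubqln2, Postn, Rab25, Ap1m2, Hexa and other named genes. The check does not cover those. Over all measured genes with another probe set, the sign was shared by 3759 of 5377 (69.9%).

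**Figure D1:**
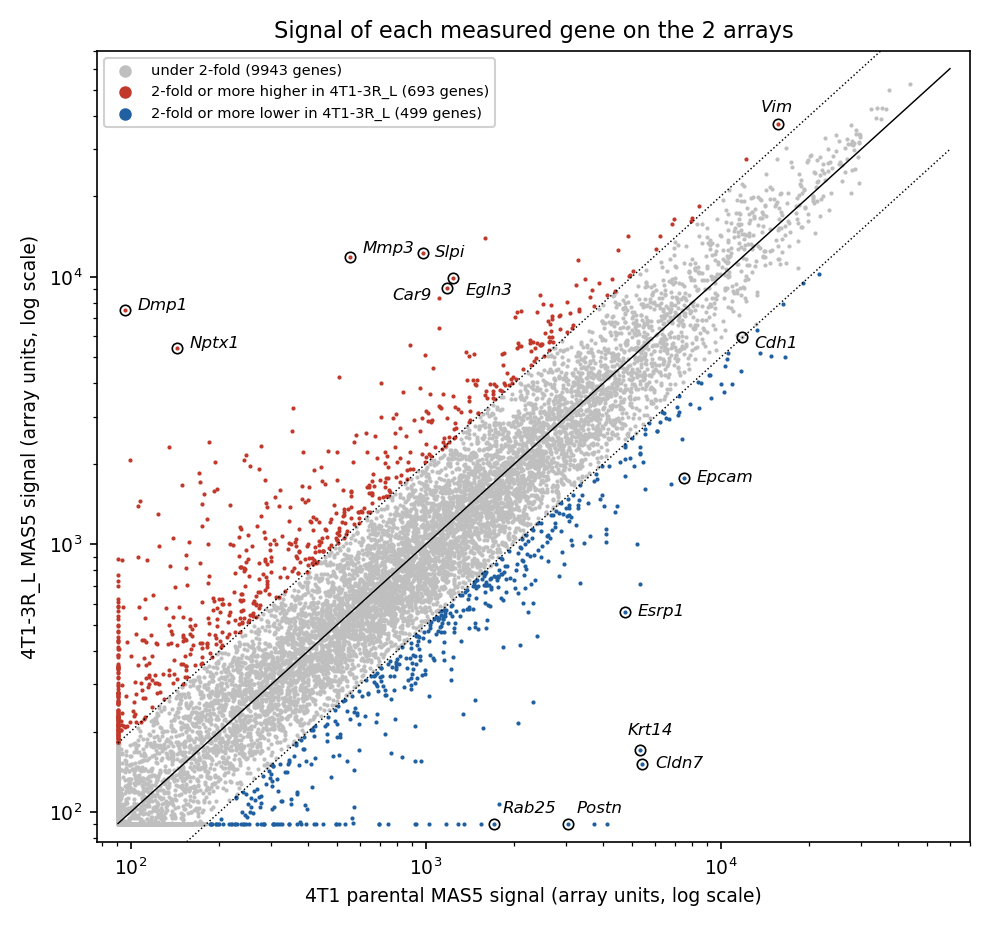
Signal of each of the 11135 measured genes in 4T1 parental cells (horizontal axis) and 4T1-3R_L cells (vertical axis), both in array units on log scales, with signals under the floor drawn at 90.6. The solid line marks equal signals and the dotted lines a 2-fold difference; 693 genes lie above the upper dotted line or on it (red) and 499 below the lower one or on it (blue), a split that turned to 250 and 2288 with the arrays scaled to the hybridisation controls.

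The rest of the 12 highest genes were led by Sema6d, a semaphorin, at 17.2-fold, although its second probe set had a log2 ratio of 0.79. The glycoprotein hormone Stc1 was 13.6-fold higher, the WNT inhibitor Apcdd1 13.1-fold, the CXXC zinc finger gene Cxxc5 13.1-fold and the secreted protease inhibitor Slpi 12.5-fold, from a signal of 979 to 12281. Niban1 was 11.1-fold, Sema7a 10.9-fold and the TNF receptor family member Tnfrsf9 10.5-fold higher. The second probe sets of Apcdd1, Cxxc5, Niban1 and Tnfrsf9 had smaller log2 ratios, of 3.05, 2.27, 2.44 and 1.42. Parental signals of Stc1 (107.5) and Cxxc5 (106.1) were close to the floor. Their log2 ratios of 3.76 and 3.72 were 3.11 and 3.05 with a floor at the 60th percentile. Among genes under the floor in parental cells, the largest lower bounds were those of the kinase gene Dmpk (at least 9.75-fold), Junos (at least 8.48-fold), the adenylate kinase Ak1 (at least 8.07-fold), the glycolate oxidase Hao1 (at least 7.70-fold), xanthine dehydrogenase Xdh (at least 6.90-fold) and the matrix protein Fbln1 (at least 6.75-fold).

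On the lower side, the cathepsin Ctsw was 16.6-fold lower in 4T1-3R_L cells, the matricellular gene Ccn4 9.56-fold, the kinase Rps6ka6 8.97-fold (log2 ratio -1.21 on its second probe set) and the epithelial splicing regulator Esrp1 8.46-fold. The drug transporter Abcg2 was 7.65-fold lower, Moxd1 7.49-fold, the small heat shock protein Hspb1 6.23-fold, Bst1 5.92-fold, the receptor kinase Ltk 5.89-fold and the myosin Myh14 5.77-fold. Signals of Ctsw (107.3), Hspb1 (91.1) and Ltk (95.4) in 4T1-3R_L cells were close to the floor. Their log2 ratios of -4.05, -2.64 and -2.56 were -3.40, -1.75 and -1.73 with a floor at the 60th percentile. Several genes with strong parental signals lay under the floor in 4T1-3R_L cells. They were Ubqln2 (at least 41.0-fold lower), the matrix protein Postn (at least 33.5-fold), the epithelial GTPase Rab25 (at least 18.9-fold), the membrane protein Mal (at least 17.1-fold on the probe set used) and the epithelial adaptor subunit Ap1m2 (at least 14.9-fold). The beta-tubulin Tubb2a was at least 45.6-fold lower, but its second probe set had a log2 ratio of -0.27.

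**Figure D2:**
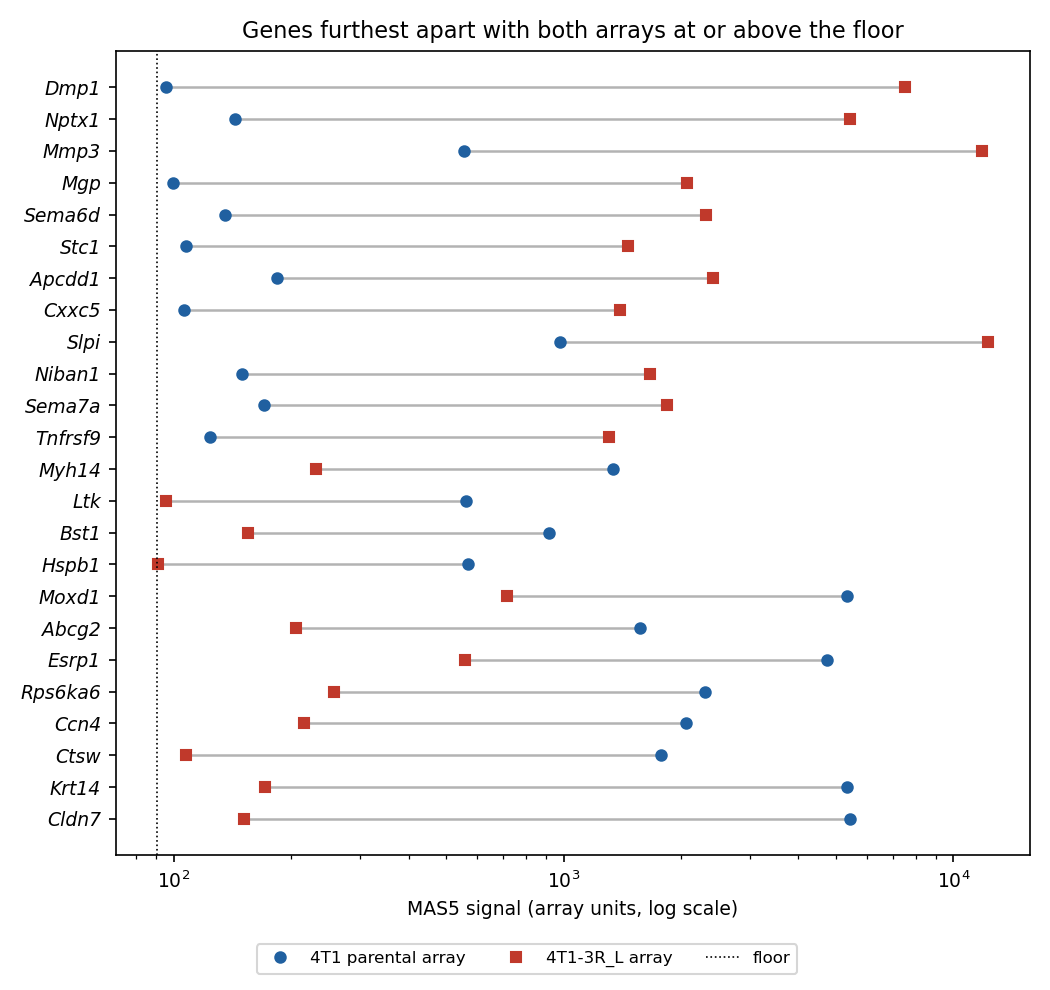
Signals of the 12 genes with the highest and the 12 with the lowest log2 ratio among genes at or above the floor on both arrays, in array units on a log axis, with 1 blue circle for the parental array and 1 red square for the 4T1-3R_L array. The dotted line is the floor of 90.6; signals ran from 95.5 to 7520 for Dmp1 and from 5432 to 151 for Cldn7.

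Epithelial genes were lower in 4T1-3R_L cells. Of 32 measured genes for epithelial junctions and keratins, 10 were at least 2-fold lower, 1 was at least 2-fold higher and 21 lay between. Besides Cldn7, Krt14 and Esrp1, the related splicing regulator Esrp2 was 5.20-fold lower and the adhesion molecule Epcam was 4.24-fold lower, but with log2 ratios of -0.51 and -0.59 on their second probe sets. Cdh1, which encodes E-cadherin, had a log2 ratio of -0.99, from a signal of 11787 to 5941. The 1 gene at least 2-fold higher was Lcn2, a secreted lipocalin also found in neutrophils, at 2.12-fold. The list median lay at -0.77 relative to all measured genes, below all random lists at percentile 0.

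Mesenchymal genes were higher as a group relative to the median gene. Of 36 members with a single-gene probe set, 12 were under the floor on both arrays. They included Cdh2 (signals of 10.5 and 26.8), Snai2 (11 and 24.1) and Twist2. Of 24 measured members, 9 were at least 2-fold higher and 2 at least 2-fold lower. Besides Mgp, the collagen chains Col6a1 and Col5a1 were 6.12-fold and 5.76-fold higher, and vimentin, Vim, was 2.38-fold higher (15605 against 37179). The 2 lower members were Postn and Thbs1, the latter 3.59-fold lower. The list median lay 0.50 above that of all measured genes, at percentile 100 of the random lists. Markers of fibroblasts and stellate cells, which also express many of these genes, moved with this group. Of 26 such markers 20 were under the floor on both arrays, and among the 6 measured the procollagen enhancer Pcolce was 8.78-fold higher, Fbln1 at least 6.75-fold, the matrix protein Ecm1 6.25-fold and the growth factor receptor Pdgfra 3.77-fold. The main fibroblast collagen transcripts Col1a1, Col1a2 and Col3a1 had 4T1-3R_L signals of 7.9, 47.2 and 29.5, all under the floor. The fibroblast list lay 2.29 above all measured genes at percentile 100, but 0.00 with a floor at the 40th percentile and 0.09 without a filter, where more of its members entered.

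Genes on the list of extracellular proteases and their inhibitors were higher relative to the median gene. This list also holds lysyl oxidases and heparanase, which are neither, so its counts and median are not those of proteases alone. Of 28 measured, 8 were at least 2-fold higher and 2 at least 2-fold lower, and the list median lay 0.76 above that of all measured genes at percentile 100. Besides Mmp3, the lysyl oxidase-like enzyme Loxl3 was 8.73-fold higher and the heparanase Hpse at least 5.95-fold higher. The 2 lower genes were Adam12 (5.63-fold) and the gelatinase Mmp9 (3.45-fold, from 5565 to 1614). Among 15 measured integrins, 5 were at least 2-fold higher and 0 at least 2-fold lower. These were Itga8 (at least 2.81-fold), Itga7 (2.64-fold), Itga1 (at least 2.54-fold), Itga6 (2.17-fold) and Itga5 (2.15-fold), of which Itga8, Itga7 and Itga1 came under 2-fold with a floor at the 60th percentile. The integrin list lay 0.33 above all measured genes, at percentile 94.3 and within the random lists, but outside them under 6 of the 10 alternatives, with a shift of 0.66 with the pseudocount and 0.53 with a floor at the 60th percentile.

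Hypoxia response genes were higher in 4T1-3R_L cells relative to the median gene, with 13 of 22 measured members at least 2-fold higher. The prolyl hydroxylase Egln3 was 7.97-fold higher (1241 against 9893), the carbonic anhydrase Car9 7.73-fold (1180 against 9119), the collagen prolyl hydroxylase subunit P4ha2 6.49-fold and the peptide hormone Adm 3.84-fold (log2 ratio 1.04 on its second probe set). Ddit4, which restrains mTOR signalling, was the 1 member at least 2-fold lower, at 2.13-fold. The list median lay 1.08 above that of all measured genes, at percentile 100. Of 17 measured glycolysis genes, 4 were at least 2-fold higher and 0 at least 2-fold lower, and the list lay 0.49 above all measured genes at percentile 99.8. The 4 were the enolase Eno2 (4.43-fold), the aldolase Aldoc (2.71-fold), the glucose transporter Slc2a1 (2.43-fold, also on the hypoxia list) and the phosphofructokinase Pfkp (2.05-fold), and 13 members lay between. Eno2 had a parental signal of 104.2, close to the floor, and its log2 ratio of 2.15 was 1.45 with a floor at the 60th percentile.

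Cholesterol synthesis genes were lower relative to all measured genes. Of 20 measured, 16 had negative log2 ratios, and 2 were at least 2-fold lower, the mevalonate pathway genes Mvd (2.65-fold) and Idi1 (2.01-fold). The list median lay at -0.56 relative to all measured genes, at percentile 0 of the random lists. Genes for fatty acid synthesis and lipid handling stayed near the median gene, at 0.01 and percentile 51.9, with 2 of 32 at least 2-fold higher, the desaturase Scd1 (2.32-fold) and the carboxylase Acacb (at least 2.24-fold). Oxidative phosphorylation genes lay at -0.12, percentile 2.52 and just within the random lists, but outside them under 3 of the 10 alternatives, with a shift of -0.25 with plain _at probe sets. Of 41 measured, 2 were at least 2-fold lower, the complex I subunit Ndufb9 (3.30-fold) and the complex III subunit Uqcrfs1 (2.30-fold).

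Of 38 measured genes of the NRF2 and glutathione list, 3 were at least 2-fold higher, the glutathione transferase Gstt1 (5.49-fold), the aldehyde dehydrogenase Aldh3a1 (2.93-fold) and the metallothionein Mt1 (2.46-fold). Gstt1 had a parental signal of 106.4, close to the floor, and its log2 ratio of 2.456 was 1.79 with a floor at the 60th percentile. Heme oxygenase, Hmox1, was 2.12-fold lower. The list lay 0.23 above all measured genes at percentile 97.7, and came within the random lists when only probe sets ending in plain _at were used, or when the median of each gene's chromosome was subtracted (percentile 95.3). For the unfolded protein and amino acid stress list the shift was -0.12 at percentile 13.6. Of its 32 measured members, the chaperone genes Dnajb9 (2.24-fold) and Pdia6 (2.09-fold) were at least 2-fold higher and the serine synthesis enzyme Psat1 was 2.13-fold lower.

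Immediate early genes, which respond to growth factor and stress signals, were higher relative to the median gene. Of 26 measured, 8 were at least 2-fold higher and 2 at least 2-fold lower. The AP-1 subunit Fosl1 was 5.14-fold higher, the zinc finger gene Egr1 4.35-fold, the phosphatase Dusp6 3.54-fold and Jun 2.98-fold, while Junb was 2.56-fold and Myc 2.16-fold lower. The list median lay 0.52 above that of all measured genes at percentile 99.96. Cell cycle genes lay slightly lower, at -0.22 and percentile 0.25. Of 44 measured, 30 had negative log2 ratios, 0 were at least 2-fold lower and 1 was at least 2-fold higher, the cyclin-dependent kinase inhibitor Cdkn1a (3.39-fold). Next in size were the inhibitor Cdkn2c (log2 ratio 0.85), the kinesin Kif20a (-0.85) and the kinase Cdk4 (-0.77).

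Of 14 measured mammary stem and progenitor genes, 3 were at least 2-fold higher, the R-spondin receptor Lgr6 (3.98-fold), the adhesion receptor Cd44 (2.35-fold) and Itga6. Cd24a, a surface marker used together with Cd44, had a log2 ratio of -0.08, and -0.90 on its second probe set. The list lay 0.12 above all measured genes, within the random lists at percentile 69.0. The list of WNT and Notch targets, which also holds ligands and receptors, lay at 0.01 and percentile 44.2. The targets Axin2, Nkd2, Sp5, Hey1, Hey2, Heyl and Hes5 were under the floor on both arrays. The list median therefore does not describe targets alone. Of 22 measured, Notum, which inactivates WNT proteins, was 3.95-fold higher, and the ligands Wnt7a (3.93-fold) and Jag1 (2.33-fold) were lower.

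Chemokines and cytokines went both ways. Of 39 measured, 10 were at least 2-fold lower and 5 at least 2-fold higher, and the list lay at 0.03, percentile 59.7. The monocyte chemoattractant Ccl2 was at least 7.69-fold lower in 4T1-3R_L cells and Cxcl16 was 5.22-fold lower. The 5 higher members were the alarmin Il33 (at least 4.58-fold), the epithelial cytokine Tslp (3.82-fold), the EGF receptor ligand Hbegf (2.84-fold), Vegfa (2.16-fold) and Il18 (2.14-fold). Csf2 and Csf3, which encode GM-CSF and G-CSF, had log2 ratios of 0.17 and 0.48. Among 24 measured chemokine and growth factor receptors, 4 were at least 2-fold higher, namely the TGF-beta co-receptor Tgfbr3 (8.54-fold, but a log2 ratio of 0.02 on its second probe set), Pdgfra (3.77-fold), Cxcr3 (3.32-fold) and Lifr (at least 3.27-fold). Erbb3 was 2.93-fold lower and Met had a log2 ratio of -0.02. The receptor list lay 0.43 above all measured genes at percentile 99.9, and within the random lists with a floor at the 40th percentile. Cxcr4, with signals of 10.8 and 27.3, and Cldn2, with 54.9 and 8.7, were under the floor on both arrays.

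The MHC class I and antigen processing list and the interferon-stimulated genes lay on opposite sides of the median gene. The first list also holds cell surface genes outside antigen presentation, Pvr, Cd47 and Cd276 among them. Of 21 measured members of this list, 4 were at least 2-fold higher, the transactivator Nlrc5 (2.51-fold), Pvr (2.25-fold), the peptide transporter Tap1 (2.17-fold) and the class I heavy chain H2-K1 (2.07-fold). The immunoproteasome subunit Psmb10 was 3.17-fold lower, and Tapbpl had a log2 ratio of -1.32. The list lay 0.50 above all measured genes at percentile 99.9. Of 40 measured interferon-stimulated genes, 30 had negative log2 ratios, and 3 were at least 2-fold lower, Rsad2 (3.50-fold), Cmpk2 (at least 3.36-fold) and Ifi47 (2.81-fold). Lgals3bp was 2.05-fold higher. The list lay at -0.23 and percentile 1.85, and came within the random lists under 3 alternatives, which were no filter, plain _at probe sets and the hybridisation control scaling, and also with chromosome medians subtracted (percentile 3.08).

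**Figure D3:**
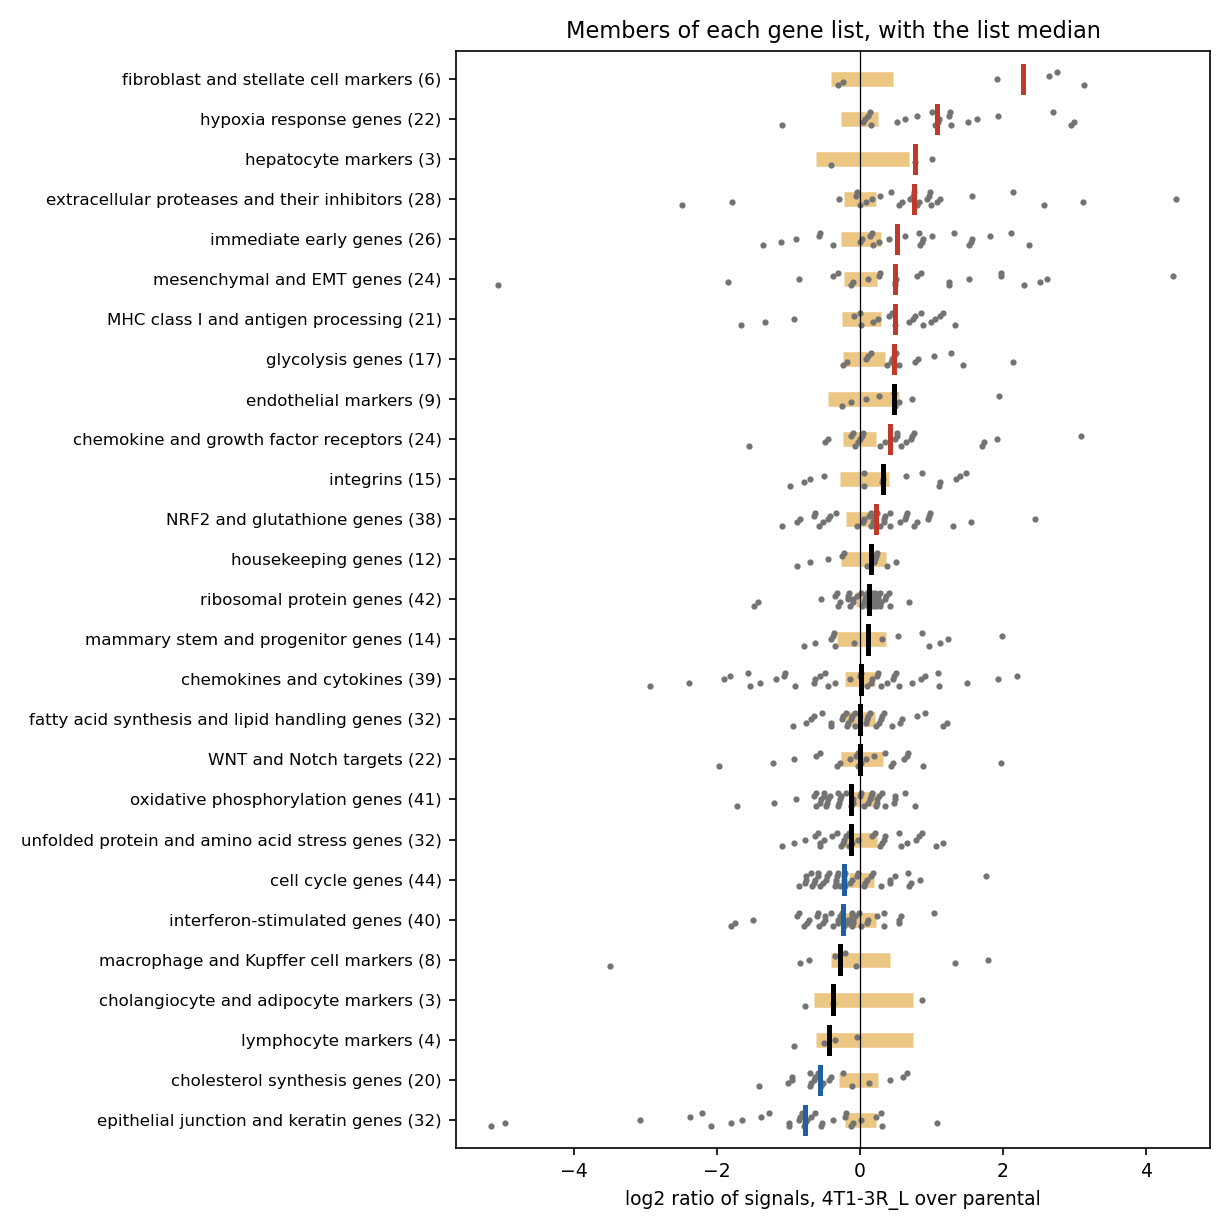
Log2 ratio of 4T1-3R_L over parental signal for each measured member (grey points) of the 27 ranked gene lists, with the number of members in brackets. The upright bar is the list median (red above, blue below and black within the random lists), and the orange band spans the central 95% of medians of 10000 random lists matched on signal. Relative to the other measured genes, 10 lists lay above the random lists and 4 below them. Lists of randomly drawn genes would give 1.35 of 27, which does not allow for list members that vary together.

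Markers of other cell types that liver tissue could carry over were mostly under the floor, with 36 measured of 173 on 8 lists, fibroblast markers included. Of 37 hepatocyte markers 34 were under it on both arrays, albumin, Alb, with signals of 11.2 and 20.8 among them. The 3 measured were Fah (2.01-fold higher), Cyp2c29 (at least 1.71-fold higher) and Arg1 (at least 1.32-fold lower), with a list shift of 0.78 at percentile 99.7 that turned to -0.14 with a floor at the 40th percentile and -0.04 without a filter. The list also came within the random lists with the pseudocount in place of the floor (percentile 95.6) and with the hybridisation control scaling (percentile 87.7), so the call was kept under 5 of 9 alternatives. Of 30 macrophage and Kupffer cell markers 8 were measured, with a shift of -0.27 at percentile 8.57 and within the random lists, but outside them under 2 of the 10 alternatives, the pseudocount in place of the floor (-0.47, percentile 1.89) and plain _at probe sets (-0.74, percentile 1.22). The colony-stimulating factor receptor Csf1r was at least 11.3-fold lower (log2 ratio -2.26 on its second probe set), the MHC class II invariant chain Cd74 was 3.48-fold higher and H2-Ab1 2.51-fold higher. Lymphocyte markers (4 measured) lay at -0.42 and percentile 8.90, with Ighm at a log2 ratio of -0.92. Endothelial markers (9 measured) lay at 0.48 and percentile 94.4, with the VEGF receptor Flt1 at 3.88-fold higher. Cholangiocyte and adipocyte markers (3 measured) lay at -0.37 and percentile 12.01; all 3 are also on the epithelial or mammary lists. The 1 measured neutrophil marker was Lcn2, and of 2 measured erythroid markers Rhd was at least 2.87-fold higher and Klf1 just reached the floor on the 4T1-3R_L array. All 6 Y-linked genes were under the floor on both arrays.

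Genes used as standards lay near the median. Of 42 measured ribosomal protein genes, 2 were at least 2-fold lower, Rpl22l1 (2.78-fold) and Rpl39 (2.68-fold). The ribosomal list lay at 0.14 and percentile 56.8, and turned to -0.07 under both quantile normalization and loess. Of 12 measured housekeeping genes 0 were at least 2-fold apart, and the list lay at 0.16 and percentile 71.6, turning to -0.03 under quantile normalization and -0.06 under loess. Among them Hprt had a log2 ratio of -0.70 and Tfrc of -0.88, with -1.03 on the second probe set of Tfrc. The log2 ratio of Actb was 0.21, but -0.36 with the arrays scaled to the hybridisation controls and 1.18 on its second probe set.

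The control probe sets differed between the arrays. The ratio of 3′ to 5′ signal for Actb was 1.22 on the parental and 1.59 on the 4T1-3R_L array, and for Gapdh 0.789 and 1.02. The 15 hybridisation control probe sets above the floor were a median of 1.49 times as bright on the 4T1-3R_L array, with a range of 1.26 to 1.76. The 14 poly-A control probe sets above the floor were a median of 2.33 times as bright, with a range of 1.481 to 2.85. Their median log2 ratio of 1.22 is larger than the medians of the hypoxia (1.08) and protease (0.75) lists, so whether these lists were higher other than relative to the median gene also depends on the scaling; scaling to the poly-A controls was not run.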

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

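Probe sets outside the gene-level comparison also differed between the arrays. Among 3090 measured probe sets with no listed gene, 14 were at least 4-fold higher in 4T1-3R_L than in parental cells and 7 at least 4-fold lower. Among 553 measured probe sets with several gene symbols, 3 were at least 4-fold higher and 5 at least 4-fold lower.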

How the results depend on the processing

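The counts of genes at least 2-fold and 4-fold apart stayed within 1.5 times their values under every alternative fixed beforehand, from 566 to 897 higher and 429 to 635 lower at 2-fold. The list shifts moved by less than the spread of random lists in 196 cases and by more in 42, some of which changed sign among lists that lay within the random lists. In 2 more cases, both for hepatocyte markers, a list that lay outside them turned sign. Epithelial, mesenchymal, protease, MHC class I, cell cycle, glycolysis, hypoxia, cholesterol and immediate early lists stayed outside the random lists, on the same side, under all 10 alternatives. Of 107 named genes at least 2-fold apart, 0 turned sign, though the extreme genes had been chosen without second probe sets of opposite sign. With at least 1 alternative fixed beforehand, 21 of the 107 came under 2-fold. Those included Idi1, Scd1, Psat1, Cd44, Wnt7a and Jag1 with the median over probe sets, and Itga8, Itga7, Itga1, Lifr, Cmpk2, Tapbpl, Acacb, Hmox1, H2-Ab1 and Rhd with a floor at the 60th percentile. No paired analysis was possible because each group has 1 array. The floor limits what is seen of dim genes, and another floor or filter changes which members of a list enter; for the other changes below the cause was not tested.

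Scaling the arrays to the hybridisation controls, chosen after seeing the data, gave 250 higher and 2288 lower at 2-fold and 58 and 150 at 4-fold, moved the fibroblast markers to 1.13 and brought 19 named genes under 2-fold, Vim among them (0.68). The following values are list shifts in log2 units. Quantile normalization gave -0.066 for ribosomal proteins and -0.034 for housekeeping genes, and loess -0.073 and -0.055. A floor at the 40th percentile gave 0.64 for proteases, 0.24 for receptors, -0.14 for hepatocyte, -0.057 for macrophage, 0.17 for endothelial, 0.0034 for fibroblast and 0.27 for cholangiocyte and adipocyte markers. A floor at the 60th percentile gave 0.53 for integrins (percentile 99.85, outside the random lists), -0.037 for macrophage, 0.19 for endothelial and 1.93 for fibroblast markers. The pseudocount in place of the floor gave 0.66 for integrins, also outside, and 2.61 for fibroblast markers. Without the filter the shifts were 0.38 for proteases, 0.68 for integrins, 0.30 for receptors, -0.045 for hepatocyte, -0.025 for macrophage, -0.032 for lymphocyte, 0.0084 for endothelial, 0.093 for fibroblast and 0.24 for cholangiocyte and adipocyte markers.

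The median over probe sets gave 0.62 for proteases, 0.28 for receptors, 0.94 for hypoxia, -0.015 for oxidative phosphorylation, -0.37 for cholesterol synthesis, 0.14 for fatty acid genes, 0.0061 for unfolded protein genes, -0.0072 for housekeeping genes and 1.81 for fibroblast markers. Plain _at probe sets gave 0.66 for mesenchymal genes, -0.11 for chemokines and cytokines, 0.36 for MHC class I and 0.86 for immediate early genes. They also gave -0.25 for oxidative phosphorylation, which was then outside the random lists at percentile 0.95, -0.24 for mammary stem genes, -0.091 for ribosomal proteins, -0.74 for macrophage markers (percentile 1.22) and 1.82 for fibroblast markers.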

Other observations

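The gene families in the next 2 paragraphs were picked by symbol after the data were seen, and the tests of fibroblast carry-over, scaling, intensity-dependent trends and culture density further down were also chosen after the result was seen. Genes for lysosomal acid hydrolases, which break down glycans, lipids and proteins in the lysosome, were higher in 4T1-3R_L cells. Of 23 measured, 20 had positive log2 ratios and 5 were at least 2-fold higher, with Hexa at 8.42-fold (276 against 2328), Ppt1 at 2.56-fold and Arsa at 2.51-fold. Their median was 0.53, at percentile 99.99 of random lists. Genes for mitochondrial ribosomal proteins were lower: of 73 measured, 11 had positive log2 ratios, 9 were at least 2-fold lower and 0 at least 2-fold higher. Mrpl16 was 3.50-fold lower (2951 against 844) and Mrpl13 2.99-fold lower (log2 ratio -0.70 on its second probe set), and the median was -0.48, at percentile 0. All 8 subunits of the CCT chaperonin had negative log2 ratios, with a median of -0.25.

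Semaphorins, their plexin receptors and neuropilins were higher, with 7 of 24 at least 2-fold higher and a median of 0.56 at percentile 99.97. Sema3c was the 1 member at least 2-fold lower, at least 10.3-fold on the probe set used but with a log2 ratio of -0.80 on its second probe set. Of 13 measured collagen chains 4 were at least 2-fold higher and 0 at least 2-fold lower, with Col18a1 at 2.59-fold and Col16a1 at 2.25-fold beside Col5a1 and Col6a1, and a median of 0.45. Of 8 measured S100 genes 3 were at least 2-fold higher, S100a16 at 9.93-fold, S100a13 at 4.17-fold and S100a1 at 2.56-fold (log2 ratio 0.56 on its second probe set), with a median of 0.63. Relative to the median measured gene, these families kept their side under quantile normalization and loess. With the arrays scaled to the hybridisation controls the family medians themselves were -0.04 for the hydrolases, -0.13 for the collagens, 0.02 for the semaphorin group, 0.06 for the S100 genes and -1.05 for the mitochondrial ribosomal proteins. Subtracting the median of each gene's chromosome gave 0.47 for the S100 genes, 0.60 for the hydrolases and 0.51 for the collagens. It gave 0.52 for the semaphorin group, -0.49 for the mitochondrial ribosomal proteins and -0.28 for the CCT subunits. Medians of the other families looked at were 0.26 for tetraspanins, -0.17 for proteasome subunits, -0.17 for tubulins and 0.02 for V-ATPase subunits. Of these 4 medians the proteasome one lay outside the random lists, at percentile 2.29.

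Measured epithelial genes were lower and measured mesenchymal genes higher as groups in the 4T1-3R_L cells, relative to the median gene. Fibroblasts or stellate cells carried over from the liver would bring their most abundant transcripts, yet the highest 4T1-3R_L signal among Col1a1, Col1a2, Col3a1, Dcn and Lum was 64.1, under the floor of 90.6. An intensity-dependent trend is argued against as the cause of the gap between the mesenchymal and epithelial medians, which was 1.27 and still 1.24 under quantile normalization and 1.23 under loess. With chromosome medians subtracted the gap was 1.21. A single scale factor per array moves both medians about alike, so the gap does not test it, but it sets the side of the mesenchymal median itself, which was 0.50 and turned to -0.075 with the arrays scaled to the hybridisation controls, so whether mesenchymal genes rose or only fell less than others stays open. A partial epithelial to mesenchymal transition was not tested. Also open is whether another culture of either population would show it, since there was 1 array of each.

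Hypoxia response genes, higher relative to the median gene, could come from the cells or from the density and oxygen of the dish at harvest. With chromosome medians subtracted the hypoxia median was 0.998 against 1.08, so chromosome-wide shifts do not account for it. The cell cycle list shifted by -0.22, which goes with a denser culture and equally with slower growing cells. With 1 culture of each population, culture conditions and cell population cannot be told apart.

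With chromosome medians subtracted the NRF2 list (percentile 95.3) and the interferon-stimulated list (3.08) came within the random lists, the macrophage list (2.46) came outside them, and the other ranked lists kept their place.

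Chromosome medians were shifted: of 20, 16 lay outside the central 95% of 2000 random gene sets matched on signal, 7 higher and 9 lower. Randomly drawn genes would give 1, and 11 lay beyond every random set. Some shifts were small, with medians of 0.07 on chromosomes 5 and 17. Chromosome 12 had a median log2 ratio of 0.28, with 72.1% of 408 genes higher, and chromosome 19 a median of -0.39, with 26.4% of 398 genes higher. Higher and lower here hold relative to the other measured genes. Scaling to the hybridisation controls moved the median of all measured genes to -0.54, and chromosome medians were not taken under it. Differences in copy number are a candidate explanation. With the gene order split in the middle, 9 of the 16 had both parts outside random sets in the direction of the whole. In 15 both parts had the sign of the whole, the exception being chromosome 15 (-0.24 and 0.06). The sign alone says little, as the second parts of chromosomes 1, 11 and 16 lay within random sets (percentiles 31.2, 11.2 and 51.5). Local gene density, a stand-in for base composition, and noise of single probe sets were argued against, as all 16 stayed outside sets matched on density and 12 were also outside on second probe sets alone. Regulation of neighbouring genes was not separated from copy number, and DNA was not analysed here.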
